A study of Mus musculus with 3 samples.

How the data were processed

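Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in mouse neural progenitor cells derived in culture from E14TG2a embryonic stem cells. The series holds 3 libraries: 1 with an antibody against Zrf1, 1 with an antibody against Ring1B and 1 with rabbit IgG as a control. Per the labels' protocols, the cells were kept in medium with EGF and FGF2, crosslinked with formaldehyde and sonicated before immunoprecipitation. The 2 peak lists analysed were 1 for Zrf1 and 1 for Ring1B. Each was assigned to its library by the antibody in its name, which occurs in the labels of 1 library alone. Reads, coverage and any peaks of the IgG library were not analysed here.

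The authors deposited each list as 3 columns with no header, namely chromosome, start and end, with no score, height, p-value, fold enrichment, summit or gene name. Per the submitters' processing notes, the tools were Bowtie 0.12.7, a short-read aligner, and MACS 1.4.2, a peak caller, with the genome build mm9. The calling threshold, the control used in calling and any later filter are not given in the sources used here, and the thresholds of the lists may differ. All intervals lay within the mm9 chromosome lengths held by GenomeInfoDb 1.38.1, while 88 Zrf1 and 97 Ring1B peaks lay past the mm10 chromosome ends. Coordinates are given as deposited, in mm9. Whether the start counts from 0 or 1 is not given, which moves a start by at most 1 bp. No 2 intervals of the same list overlapped or touched.

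The plan fixed before the data were examined also held gene-level comparisons, gene lists, promoter classes and a comparison of peak scores. These were not run. The lists carry no scores or gene names, the gene table at hand is for another assembly (GRCm38.p6), and coordinates were not converted between builds. That table was used only for the chromosomes that carry Hox genes, in the closing section. The planned rule for named items (the 10 best per class by score) was applied with peak width in place of the score. Width is not a measure of peak strength. The comparison of widths, the X chromosome test and the cluster analysis were likewise chosen after the lists had been seen.

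From the intervals, peak width was computed as end minus start. A peak was counted as shared if it overlapped a peak of the other list by at least 1 bp. The observed count was set beside 1000 random circular shifts (seed 20), in which all Zrf1 peaks of a chromosome moved together by a random distance of at least 1 Mb within the span of its peaks. Shares are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Widths of shared and unshared peaks were compared within each list by the difference of medians, with a 2-sided permutation test over peaks (100000 permutations). The X chromosome and the autosomes were compared with 2-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over 2 tests. Clusters were runs of peaks of 1 list with gaps of at most 5 kb. Peaks are not replicates and neighbouring peaks are not independent, so these tests describe the 2 lists, not the repeatability of either immunoprecipitation.

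Each antibody had 1 library and no replicate, so no difference carries an error between samples. The depth of the libraries is unknown from the lists, and the number of peaks depends on depth, antibody and threshold together. Alternatives changed the overlap rule, the chromosomes used, the random placement, the peak extent and the cluster gap, and those added after the data were seen are named in the closing section. The overlap code was tested on simulated data: 1158 of 1158 planted overlaps among 12659 simulated Zrf1 and 11696 simulated Ring1B peaks were recovered, and shifts of the simulated peaks gave a mean of 154.5 overlaps against 154.5 expected from widths and density. Counts at 1 bp, at 50% coverage and at reciprocal 50% equalled those of bedtools 2.31.1, with coverage summed over all peaks of the other list; counting only a single covering peak gave 1892 Zrf1 and 1573 Ring1B peaks at 50%, against 1894 and 1590. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.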

Results

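The genome-wide positions of Zrf1 and Ring1B were mapped in neural progenitor cells grown from mouse embryonic stem cells. Zrf1, encoded by Dnajc2, is a chromatin-associated and chaperone-related protein known to bind ubiquitylated histone H2A. Ring1B, encoded by Rnf2, is the ubiquitin ligase of Polycomb repressive complex 1 that places this mark. The design asked how the binding profiles of the 2 proteins compare in these cells. One library per antibody was available, so every statement below concerns those libraries, and read depth is unknown from the deposited intervals.

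Zrf1 and Ring1B gave lists of nearly equal length but of different shape. The Zrf1 list held 11647 peaks and the Ring1B list 11790 peaks. Ring1B peaks were wider, with a median of 1324 bp (quartiles 987 and 1764 bp), against 796 bp (quartiles 639 and 1027 bp) for Zrf1. Ring1B peaks covered 17.9 Mb, which is 0.674% of the mm9 chromosomes, and Zrf1 peaks covered 10.6 Mb, or 0.401%. The Ring1B list held 117 peaks over 5000 bp and the Zrf1 list 14. Ring1B peaks also lay closer together: 1736 of the gaps between neighbouring peaks (14.7%) were at most 5 kb, against 895 (7.70%) in the Zrf1 list. Among these were 327 Ring1B gaps (2.78%) and 61 Zrf1 gaps (0.525%) of at most 100 bp. The widths depend on the calling settings and depth of each library, so their difference between lists was not tested.

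Peaks of both proteins were found on all 19 autosomes and were sparse on the X chromosome. On the autosomes the lists had almost the same mean density, 4.68 Zrf1 and 4.72 Ring1B peaks per Mb. Chromosome 11 was the densest in both lists, with 7.79 Zrf1 and 8.42 Ring1B peaks per Mb, and chromosome 14 the least dense autosome, with 2.94 and 3.20. The X chromosome carried 71 Zrf1 peaks (0.426 per Mb) and 130 Ring1B peaks (0.780 per Mb), below every autosome. Its copy number and read depth were not examined, so fewer peaks there do not show less binding. Of the 71 Zrf1 peaks, 20 fell into 2 clusters near the distal end of the X chromosome, between positions 166499862 and 166632874. The Y chromosome carried 2 Zrf1 peaks and no Ring1B peak. Across 2569 windows of 1 Mb on the autosomes and X, the numbers of Zrf1 and Ring1B peaks rose together (Spearman's rho 0.77 across windows, which are not replicates).

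**Figure D1:**
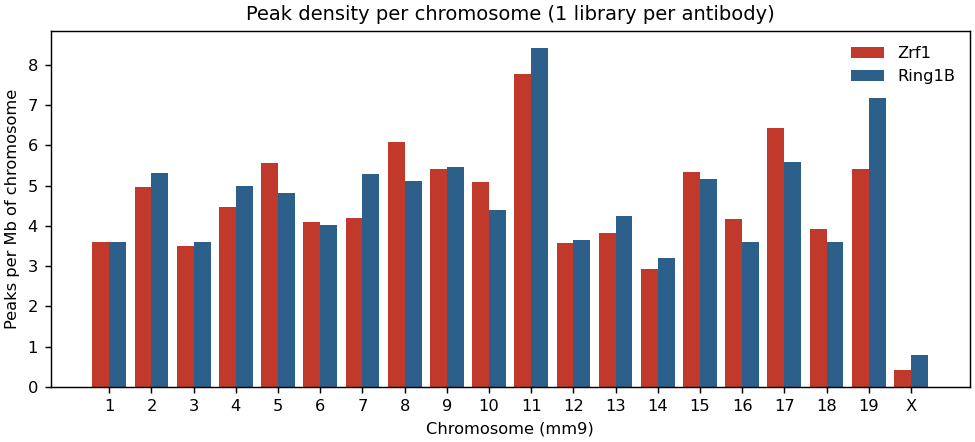
Peaks per Mb of chromosome (vertical axis) for each mm9 chromosome (horizontal axis) in the Zrf1 list (red bars) and the Ring1B list (blue bars), 1 library each. Chromosome 11 is the densest in both lists (7.79 and 8.42 peaks per Mb), and the X chromosome carries 0.426 and 0.780 peaks per Mb.

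A minority of each list coincided with the other, far more than at shifted positions. Of the 11647 Zrf1 peaks, 1976 overlapped a Ring1B peak, which is 17.0% (95% interval 16.3 to 17.7%). Of the 11790 Ring1B peaks, 1956 overlapped a Zrf1 peak, which is 16.6% (95% interval 15.9 to 17.3%). The remaining 9671 Zrf1 peaks and 9834 Ring1B peaks overlapped no peak of the other protein. When the Zrf1 peaks of each chromosome were shifted at random, 139 ± 13.6 (SD, 1000 shifts) overlapped a Ring1B peak, with a range of 98 to 185. The observed number was thus 14.2-fold the mean of the shifts for Zrf1 and 13.9-fold for Ring1B, and none of the 1000 shifts reached it. Shifts of only 20 to 100 kb, which keep the peaks in their neighbourhood, gave a mean of 317 overlaps (range 261 to 375), and the observed number was 6.24-fold that mean.

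The shared peaks were closely aligned. Over the 1995 overlapping pairs the median distance between the centres of the Zrf1 and the Ring1B peak was 165 bp (quartiles 69.3 and 366 bp), and 83.4% of the pairs had centres within 500 bp. At the median, 97.4% of a shared Zrf1 peak was covered by Ring1B, and 835 of the 1976 shared Zrf1 peaks (42.3%) lay wholly inside Ring1B peaks. Conversely, 223 shared Ring1B peaks lay wholly inside Zrf1 peaks. Pairs chosen for overlapping have near centres in part by that choice, and these distances were not computed after shifts. With a reciprocal overlap of 50%, 1535 of the 1976 shared Zrf1 peaks remained. After shifts a mean of 33.0 met that rule, while a mean of 139 overlapped at all. In bases, the shared sequence of 2117978 bp made up 19.9% of the Zrf1-covered and 11.8% of the Ring1B-covered sequence. Moving all Zrf1 peaks by 1 kb left a mean of 1512 overlaps over both directions, by 2 kb 520, and by 5 kb 339.

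**Figure D2:**
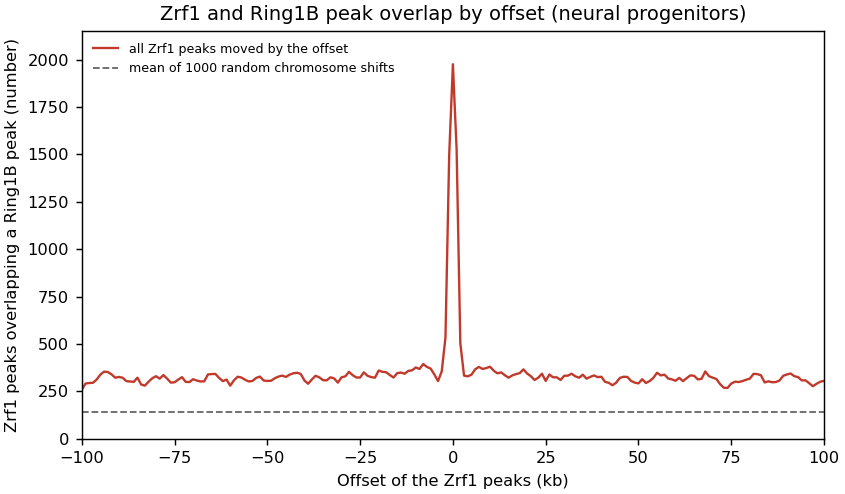
Number of Zrf1 peaks that overlap a Ring1B peak (vertical axis) after all Zrf1 peaks are moved by the same offset in kb (horizontal axis, red line), with the mean of 1000 random chromosome shifts as a dashed line. The count is 1976 at the deposited positions, falls to a mean of 339 at 5 kb, and stays above the dashed line at 139 out to 100 kb, where the mean is 282.

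Peaks that were not shared also lay closer to the other protein than shifted peaks did. Among the 9671 unshared Zrf1 peaks, 790 (8.17%) had a Ring1B peak within 5 kb, against a mean of 4.28% and a range of 3.75 to 5.04% over 100 shifts. Within 50 kb the share was 52.3%, against a mean of 28.4% (range 26.5 to 31.0%). For unshared Ring1B peaks, 9.60% had a Zrf1 peak within 5 kb, against a mean of 4.57% (range 4.03 to 5.47%). These shifts ran along the whole chromosome and so did not keep the regional density that both lists share. Whether unshared peaks lay closer than that density gives was not tested.

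Shared Zrf1 peaks were wider than the rest of the Zrf1 list. Their median width was 1093 bp (quartiles 868 and 1426 bp, 1976 peaks), against 754 bp (quartiles 623 and 942 bp, 9671 peaks) for unshared Zrf1 peaks. The difference of 339 bp had a 2-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Wide peaks also overlapped more often after shifts, where the same difference averaged 43.5 bp and reached at most 149 bp. The share of Zrf1 peaks on a Ring1B peak was 3.35% (39 of 1165) in the narrowest decile of the Zrf1 list and 45.7% (532 of 1164) in the widest, while shifted peaks gave 1.03% and 1.67%.

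In the Ring1B list the relation of width to sharing was smaller. Shared Ring1B peaks had a median width of 1426 bp (1956 peaks) and unshared ones 1306 bp (9834 peaks), a difference of 121 bp with a 2-sided permutation p of 1e-05. This was no larger than after shifts, since 853 of the 1000 shifts gave a difference at least as large, with a mean of 189 bp. The difference was 6 bp with a reciprocal overlap of 50% (permutation p = 0.779) and -81 bp with peaks reduced to their central 200 bp (permutation p = 6e-04), so its direction depends on how sharing is defined. By width decile, the share of Ring1B peaks on a Zrf1 peak went from 13.0% (153 of 1179) to 21.6% (255 of 1179), against 0.789% and 2.16% in shifted lists. The widest 1% of Ring1B peaks fell outside this rise, with 13 of 117 on a Zrf1 peak (11.1%, 95% interval 6.05 to 18.3%). The slopes of the 2 lists were not tested against each other.

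**Figure D3:**
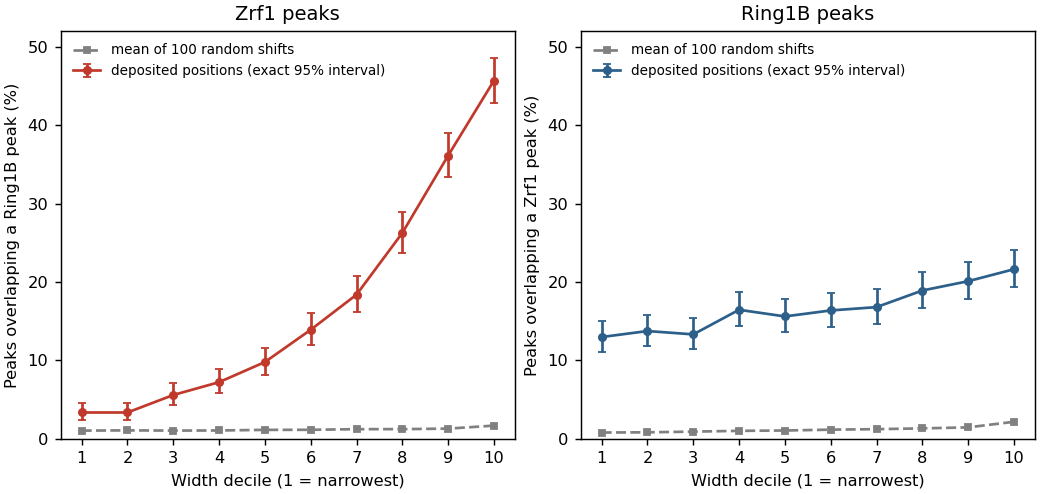
Share of peaks overlapping a peak of the other list in percent (vertical axis) by width decile within the list (horizontal axis, 1 is the narrowest), for Zrf1 peaks (left) and Ring1B peaks (right), with exact 95% binomial intervals and the mean of 100 random shifts (grey). The Zrf1 share runs from 3.35% to 45.7% and the Ring1B share from 13.0% to 21.6%, while the shifted lists stay at or below 2.16%.

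The amount of sharing varied between chromosomes, and the X chromosome had a smaller share than every autosome in both lists. The X chromosome was compared with the autosomes after the lists had been seen. Among autosomes the share of Zrf1 peaks on a Ring1B peak ran from 13.7% on chromosome 16 to 23.0% on chromosome 7, and that of Ring1B peaks on a Zrf1 peak from 12.7% on chromosome 13 to 22.0% on chromosome 15. On the X chromosome 7 of 130 Ring1B peaks (5.38%, 95% interval 2.19 to 10.8%) overlapped a Zrf1 peak, against 16.7% of the autosomal Ring1B peaks (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000385). For Zrf1, 7 of 71 X-linked peaks (9.86%, 95% interval 4.06 to 19.3%) overlapped a Ring1B peak, against 17.0% on the autosomes, which did not pass (Fisher's exact test, adjusted p = 0.151). Both tests count the same overlaps, seen from either list. Peaks were also sparser on the X chromosome, with 0.426 against 4.68 Zrf1 and 0.780 against 4.72 Ring1B peaks per Mb. Lower density alone gives fewer overlaps, and the X chromosome was not set beside shifts by itself. Zrf1 density on the X chromosome was 0.091 of the autosomal density. The odds that a Ring1B peak there overlapped Zrf1 were 0.284 of the autosomal odds. For Zrf1 peaks on Ring1B, the Ring1B density ratio was 0.165 and the odds ratio 0.534. Overlap thus fell by less than density, and the smaller share does not show less sharing relative to density. Sharing relative to density was not tested.

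The widest Zrf1 peaks lay on Ring1B more often than the whole list, and the widest Ring1B peaks did not lie on Zrf1 more often. Of the widest 1% of Zrf1 peaks, 50 of 116 (43.1%, 95% interval 33.9 to 52.6%) overlapped a Ring1B peak, against 17.0% of the whole list. The peaks named next were chosen by class. Ranked by the worse of the 2 width ranks, 8 of the 10 leading shared pairs lay in a single region of chromosome 6. There a Ring1B peak of 23645 bp (47687021 to 47710666), the widest of its list, and 2 further Ring1B peaks faced a run of 8 Zrf1 peaks between 47688679 and 47723566. The other 2 pairs were on chromosome 1, where a Zrf1 peak of 7101 bp (172998136 to 173005237) overlapped a Ring1B peak of 4794 bp, and on chromosome 15, where a Zrf1 peak of 2400 bp (76062002 to 76064402) overlapped a Ring1B peak of 4951 bp. The 10 widest peaks of Ring1B alone measured 10136 to 12861 bp, led by chromosome 6 from 47602144 to 47615005 and chromosome 11 from 96149958 to 96162771. Others lay on chromosome 5 from 102085759 to 102097803 and from 106880140 to 106891595, and on chromosome 4 from 109646514 to 109657691. None of these 10 lay within 1 Mb of the first or last peak of its chromosome.

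The 10 widest peaks of Zrf1 alone measured 4666 to 12690 bp, led by chromosome 7 from 71220995 to 71233685. Of these, 4 lay within 1 Mb of the first or last peak of their chromosome, namely chromosome 16 from 3231417 to 3241548, chromosome 17 from 3025068 to 3034321, chromosome 4 from 3006247 to 3013834 and the X chromosome from 166609316 to 166616336. Without these outer parts of each chromosome, 1910 of 11379 Zrf1 peaks (16.8%) overlapped a Ring1B peak. The genes and sequence at these positions were not analysed here.

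Few of the Ring1B peaks in the 4 largest Ring1B clusters overlapped Zrf1, at about the level of shifted positions. These clusters were examined after the lists had been seen. The 4 Ring1B clusters with the most covered sequence spanned chromosome 6 from 52135677 to 52225817 (21 peaks covering 63.7 of 90.1 kb), chromosome 11 from 96112328 to 96188865 (20 peaks, 53.4 of 76.5 kb), chromosome 2 from 74486948 to 74554487 (21 peaks, 52.4 of 67.5 kb) and chromosome 15 from 102782855 to 102852418 (16 peaks, 39.5 of 69.6 kb). The first 3 contained no Zrf1 peak and the fourth contained 2. Together, 2 of their 78 Ring1B peaks (2.56%, 95% interval 0.312 to 8.96%) overlapped Zrf1, against 16.7% of the other 11712 Ring1B peaks and a mean of 1.87% after 100 shifts. The Zrf1 density of their chromosomes gives 1.67 Zrf1 peaks in these spans, too few for any count to show depletion per base. Over all 61 clusters of 5 or more peaks, the mean share of Ring1B peaks on Zrf1 per cluster minus that of lone peaks was -9.59 percentage points (permutation p = 0.041). This missed the threshold with gaps up to 10 kb (-3.55, permutation p = 0.349), with peaks within 1 kb (-8.54, permutation p = 0.0944) and without the 4 largest clusters (-9.25, permutation p = 0.0549). Any overlap was held by 29.5% of these clusters and 17.5% of lone peaks, against means of 7.93% and 1.15% after shifts. The fifth cluster, chromosome 6 from 47687021 to 47728897, was the region shared with the run of 8 Zrf1 peaks. There 3 of 4 Ring1B peaks overlapped Zrf1, and the share of the 4 largest clusters leaves them out. Of the 20 Ring1B clusters with the most covered sequence, 15 contained no Zrf1 peak and 5 did. These are not all separate regions. The clusters on chromosome 2 from 74561809 to 74591852 and chromosome 6 from 52102250 to 52130010 contained no Zrf1 peak. They lay within 10 kb of 2 of the 4 largest clusters, and stayed in when those 4 were left out.

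**Figure D4:**
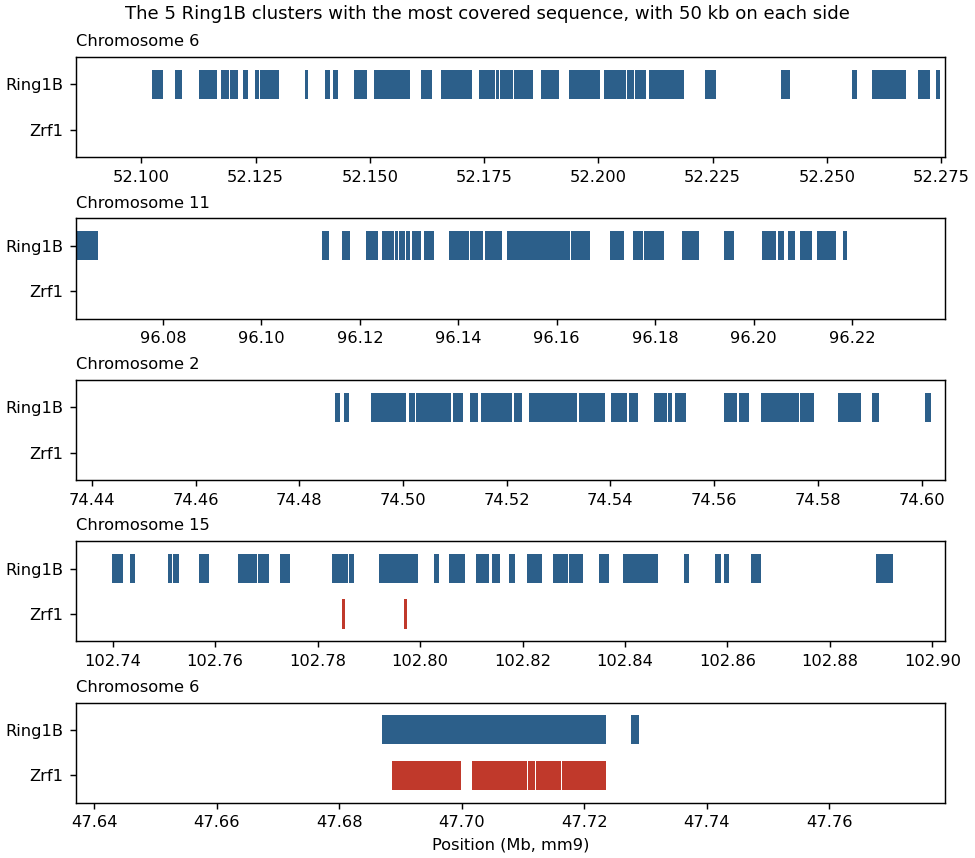
Map of the 5 Ring1B clusters with the most covered sequence, with 50 kb on each side, showing deposited Ring1B peaks (blue) and Zrf1 peaks (red) by mm9 position in Mb (horizontal axis). The first 3 clusters contain no Zrf1 peak, the cluster on chromosome 15 contains 2, and the fifth contains 8.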

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

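The settings with the wider peaks, central 200 bp, merging, starts from 1, short shifts and no chromosome ends, and all tests of width, X chromosome and clusters, were chosen after seeing the data. Comparisons by score, false discovery rate, gene or promoter, set before the data were examined, were not run, because the lists hold intervals only. The count of shared peaks stayed within 1.5 times its value with 50% coverage, reciprocal 50%, a distance within 1 kb, autosomes and X, merging, starts from 1 and no chromosome ends. It was 1024 (Zrf1) and 1000 (Ring1B) among peaks of at least the median width, and 1115 in both lists with central 200 bp, where fewer or smaller intervals entered. The fold over shifts (14.2 and 13.9) ranged from 6.13 to 47.9. It was 21.3 and 40.1 at 50% coverage, 46.5 in both lists at reciprocal 50%, 8.71 and 8.66 within 1 kb, 21.5 and 21.0 among the wider peaks, 47.9 in both with central 200 bp, and 6.24 and 6.13 for shifts of 20 to 100 kb. Shared Zrf1 peaks were wider in both alternatives. For Ring1B the difference was 6 bp (permutation p = 0.779) at reciprocal 50% and reversed to -81 bp (permutation p = 6e-04) with central 200 bp, and the cause was not tested. The lower share of Ring1B peaks on Zrf1 on the X chromosome, not adjusted for the lower peak density there, passed in all 8 alternatives run. For Zrf1 it passed in 2 of 8, at -9.28 percentage points with 50% coverage (Fisher's exact test, adjusted p = 0.0348) and -14.7 among the wider peaks (Fisher's exact test, adjusted p = 0.0429, 1 of 34 X peaks), and the cause was not tested. The share of peaks on Zrf1 in large Ring1B clusters minus that of lone peaks, -9.59 percentage points (permutation p = 0.041), was -13.7 (permutation p = 0.0403) with gaps up to 2 kb. It missed the threshold at -3.55 (permutation p = 0.349) with gaps up to 10 kb, -8.54 (permutation p = 0.0944) within 1 kb and -9.25 (permutation p = 0.0549) without the 4 largest clusters. The difference in Ring1B bases covered by Zrf1 missed it at -5.67 (permutation p = 0.0764) with gaps up to 10 kb, and passed with gaps up to 2 kb and without the 4 largest; the causes were not tested. Depth is unknown, so absence of a peak does not show absence of binding.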

Other observations

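All tests of explanations, clusters, chromosome ends and HOX chromosomes were chosen after the lists were seen, and those of length bias by list, splitting and HOX chromosomes also after the results they bear on. Clusters of Ring1B peaks showed how sharing varied with local density. Of 10054 clusters, 8915 were lone peaks, 1078 held 2 to 4 peaks and 61 held 5 or more. Zrf1 overlapped 17.5% of lone Ring1B peaks (1560 of 8915), 15.0% of those in clusters of 2 to 4 (366 of 2443) and 6.94% of those in clusters of 5 or more (30 of 432, 95% interval 4.73 to 9.77%). The last share was still above that of all 100 shifts (mean 1.46%, highest 3.47%). Counted per cluster, 29.5% of the 61 large clusters (18, 95% interval 18.5 to 42.6%) held at least 1 Ring1B peak on Zrf1, against 17.5% of lone peaks, while shifts gave means of 7.93% and 1.15%. The Zrf1 list had its own dense regions: the cluster with the most covered sequence held 17 peaks on the X chromosome from 166578494 to 166632874, followed by 8 on chromosome 6 from 47688679 to 47723566 and 10 on chromosome 3 from 3000056 to 3033391. The clusters on the X chromosome and chromosome 3 lay within 1 Mb of the first or last peak of their chromosome. So did 6 of the 20 Zrf1 clusters with the most covered sequence, against 1 of 20 for Ring1B. Whether IgG was also enriched in these regions was not examined. Of the widest 1% of Zrf1 peaks (116 peaks), 15.5% lay within 1 Mb of the first or last peak of their chromosome, against 2.17% of the other Zrf1 peaks (Fisher's exact test, unadjusted p = 1.38e-10), while the widest 1% of Ring1B peaks had 1.71% there against 2.73%. Neighbouring peaks, such as those of the end clusters above, were counted one by one, so this p-value overstates the evidence.

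The excess of shared peaks over shifted peaks was set against 3 technical explanations. Regional clustering of both lists as the whole cause is argued against, since shifts of 20 to 100 kb kept a mean of 16.0% of the observed overlaps and at most 19.0%. Peak width was already held in the shifts, which keep the width of every peak, so width alone gives no excess over them. With the central 200 bp of the peaks the overlap was 47.9-fold that of shifted peaks. This shows that the excess holds for short intervals of equal length, and adds no separate evidence on width as a cause. Regions enriched with any antibody stay open, because 0 peak lists of the IgG library were analysed, and shared promoters or open chromatin could produce the same alignment. Co-occupancy of the same DNA by both proteins is a biological explanation that was not tested.

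The greater width of shared peaks was set against length bias of overlap, the tendency of wide intervals to overlap more often. For Zrf1, 0 of 1000 shifts gave a difference as large as the observed 339 bp. The shifts held a mean of 139 overlapping Zrf1 peaks, against 1976 observed, so by themselves they cannot decide. With sharing called on the central 200 bp, every interval compared has the same length. Shared Zrf1 peaks were then still wider, by 328 bp (permutation p = 1e-05). This argues against length bias of overlap as the whole cause for Zrf1. For Ring1B, 853 of 1000 shifts gave a difference at least as large as the observed one, which thus did not exceed length bias at shifted positions. Those shifts held a mean of 141 overlapping Ring1B peaks, against 1956 observed. With sharing called on the central 200 bp, the Ring1B difference was -81 bp (permutation p = 6e-04). Length bias among the observed overlaps may differ from that in the shifts, so whether it explains the Ring1B difference stays open. A candidate explanation for the Zrf1 difference is that stronger or broader Zrf1 signal lies at Ring1B sites, which was not tested because the list holds no signal values. A larger share of false or weak calls among narrow Zrf1 peaks is an equally open one.

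The low share of peaks on Zrf1 in the largest Ring1B clusters rests on a weak difference per cluster (permutation p = 0.041), which missed the threshold in 3 of 4 alternatives. Against splitting of broad regions into several peaks, Zrf1 covered 3.63% of Ring1B bases in large clusters and 12.9% in lone peaks (permutation p = 0.0177, and 0.0764 in a permutation test with gaps up to 10 kb). Lone peaks matched on width had a share of 19.9% on Zrf1 against 6.94% in large clusters. Splitting itself lowers a share counted per peak, so this comparison cannot decide on splitting. Splitting stays open, since the base share loses its call with wider gaps and lone peaks (11.2 to 13.7% over width deciles) average 1.44 kb of Ring1B against 15.3 kb per large cluster, and the fold over shifts (3.72, from 2.25 to 12.2, against 15.2, from 12.6 to 18.4) has a ceiling of 12.6 for large clusters. A hypothesis is that the 4 largest clusters are the HOX gene clusters, classical Polycomb targets that encode transcription factors of body patterning: they lie on chromosomes 6, 11, 2 and 15, where the gene table places the Hoxa, Hoxb, Hoxd and Hoxc genes. Of 100000 random draws of 4 from the 61 large clusters, 0.064% fell on these 4 chromosomes with 1 on each, but this test uses chromosome names only and shows no position. The hypothesis was set after these clusters were seen, so the draws add no independent support.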
